A study of Homo sapiens and Mus musculus with 17 samples.

How the data were processed

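Chromatin immunoprecipitation and sequencing data were analysed for 17 libraries. The 6 mouse libraries came from dendritic cells of the C57BL/6 strain that had received lipopolysaccharide (LPS) at 0.1 ug/ml, a bacterial product that activates these cells. Histone H3 lysine 4 trimethylation (H3K4me3), a mark of promoters in use, was profiled in them on the Ion Torrent semiconductor sequencer from 56, 4 and 0.4 ng and once on Illumina. RNA polymerase II (Pol II) was profiled once on each platform. The 11 human libraries were all sequenced on Ion Torrent. They comprised H3K4me3 and H3K27me3, the Polycomb-deposited mark of silenced promoters, in the melanoma cell lines WM115 and WM266-4, and H3K4me3 in 7 melanoma tumours. Per the labels, the antibody was used at 1 ug/ml for H3K4me3, 5 ug/ml for H3K27me3 and 10 ug/ml for Pol II. The mark of the tumour libraries is stated in their titles only, and the step at which the ng amount was measured is not given in the sources used here.

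The submitters' processing notes name the aligner BWA, with no version, and the genome builds mm9 and hg19; mouse coordinates were read as mm9 and human coordinates as hg19. The 15 H3K4me3 and Pol II lists were deposited as segments, 1 list per library, each segment with a score from the authors. The peak caller, its threshold and the meaning of the score are not given in the sources used here, so the score served only to rank regions within 1 list. For H3K27me3 the authors deposited a whole-number count for each of 23250 promoter windows of 2 kb, each named by a transcript and a gene symbol. The plan, fixed before the data were examined, had assumed H3K27me3 peaks; with counts per window, a promoter was instead called marked at 3 times its library's median count or more. That multiple was set after the distribution of counts was seen and before any gene list was counted. Total counts were 383365 in WM115 and 446954 in WM266-4, with medians of 13 and 11 per promoter. Windows of neighbouring genes can overlap and share reads, so intervals on these counts are too narrow. Read totals of the other 15 libraries were not used here, and their depth is unknown.

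Segments longer than 100 kb and segments on the Y chromosome, the mitochondrial genome and separate contigs were left out. Some of these contigs are assigned to a chromosome. Remaining segments that shared 1 bp were merged into regions, each with the score of its widest segment. Ion Torrent lists stopped part way along many chromosomes, often with a closing segment of over 1 Mb. The stretch of each chromosome up to the last segment of at most 100 kb was therefore taken as called, and lists were compared over the stretch called in every list compared. That restriction was chosen after values over whole chromosomes had been seen, and those values stand beside the main ones. Regions overlapped when they shared 1 bp. The overlap expected by chance came from 100 rotations of the second list along the shared stretch. Shares have 95% Wilson intervals, which cover counting error only.

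A promoter carried H3K4me3 when a region touched the stretch within 1 kb of the transcription start given by its deposited window. After removal of Y-linked promoters, XIST and TSIX, 23149 windows were used. Each symbol has 1 window, so alternative promoters of a gene are not covered. Of the deposited windows, 23042 matched the gene name table by transcript or symbol. The 16 human gene lists were fixed with that plan and covered cell types, developmental regulators, cancer-testis antigens, antigen presentation, the cell cycle, adhesion and housekeeping. The 7 mouse lists were not analysed here because no mm9 annotation was used, and mouse regions are given by position.

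The rule for genes named in the text was also fixed beforehand. It allows every gene of the fixed lists as an example. For each comparison of 2 lists it takes the 10 genes with the highest score that have a promoter region in one list and no region within 5 kb in the other (3 regions per direction in mouse). For genes with both marks or opposite marks it takes the 10 with the highest sum of ranks, and for tumours against lines the 10 per direction with the highest mean rank. Y-linked genes, XIST and genes with no official symbol are passed over; systematic symbols of the FAM, open reading frame, LINC, MIR, SNOR and antisense kinds were passed over too, which goes beyond the written rule. For H3K27me3 the rule was adapted to counts: marked in one line and at most 1 times the median in the other, ranked by the multiple of the median. Any other gene named was chosen after its values were seen, and the text says so. Some genes that the rule allows are not reported here.

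The 7 tumours and the 2 lines were compared by an exact two-sided permutation test of the share of each gene list. The two-sided p was the smaller one-sided p doubled, which over 36 splits is at least 0.0556, so no list could reach significance at the usual level by it. Added after the data were seen, a p from the absolute difference can go down to 0.0278. Benjamini-Hochberg adjustment ran over the 16 lists. Mouse libraries and line libraries have no replicates, so no test was made between them. Gene lists in the lines were set against 10000 random lists of the same size, matched on mean level for the H3K27me3 fold, which used a pseudocount of 1. The labels do not say whether the tumours came from separate patients, so p-values measure only the spread between these samples, which may be technical. The 2 lines come from the same patient and are not independent of each other, although the test treats them as separate samples. The code was tested on simulated data: of 2000 simulated regions, the 1200 planted overlaps were found with 0 false ones; of 23149 simulated promoters, the 200 raised H3K27me3 counts were found with 0 false calls; and independent simulated lists overlapped at 1.52% against 1.49% under rotation. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

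Alternatives fixed with that plan were the better part of each list by score, lists shortened to the length of the shortest, an overlap of at least 50% of the shorter region, the other direction of each overlap, a promoter within 2.5 kb, a region covering at least 50% of the promoter, autosomes only, and leaving out each tumour. Added after the data were seen were whole chromosomes, a stretch ended at the first segment over 1 Mb, unmerged segments, segments of up to 30 kb, H3K27me3 marks at 2 or 4 times the median or scaled by the total, tumour genes called in all 7 tumours, WM266-4 left out, a p from the absolute difference, and random lists matched on level and X linkage.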

Results

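Region lists of H3K4me3 and Pol II were compared across sequencing platforms and amounts of input in mouse dendritic cells, and H3K4me3 and H3K27me3 were compared across melanoma cell lines and tumours. WM115 comes from a primary melanoma and WM266-4 from a metastasis of the same patient. There was 1 library per condition, except for the 7 tumours. In mouse, the Illumina lists held 29824 H3K4me3 and 31192 Pol II regions. On Ion Torrent there were 6626 H3K4me3 regions at 56 ng, 9832 at 4 ng and 35707 at 0.4 ng, the longest mouse list, and 11750 Pol II regions. WM115 had 7781 H3K4me3 regions, WM266-4 had 4260 and the tumours 18162 to 27349. Ion Torrent lists covered only the first part of many chromosomes. Both Illumina lists were called over at least 99.8% of the genome, but 56 ng over 47.3%, 4 ng over 60.2%, 0.4 ng over 75.4%, Pol II over 58.4%, WM115 over 38.7%, WM266-4 over 19.2% and the tumours over 71.8 to 97.0%.

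**Figure D1:**
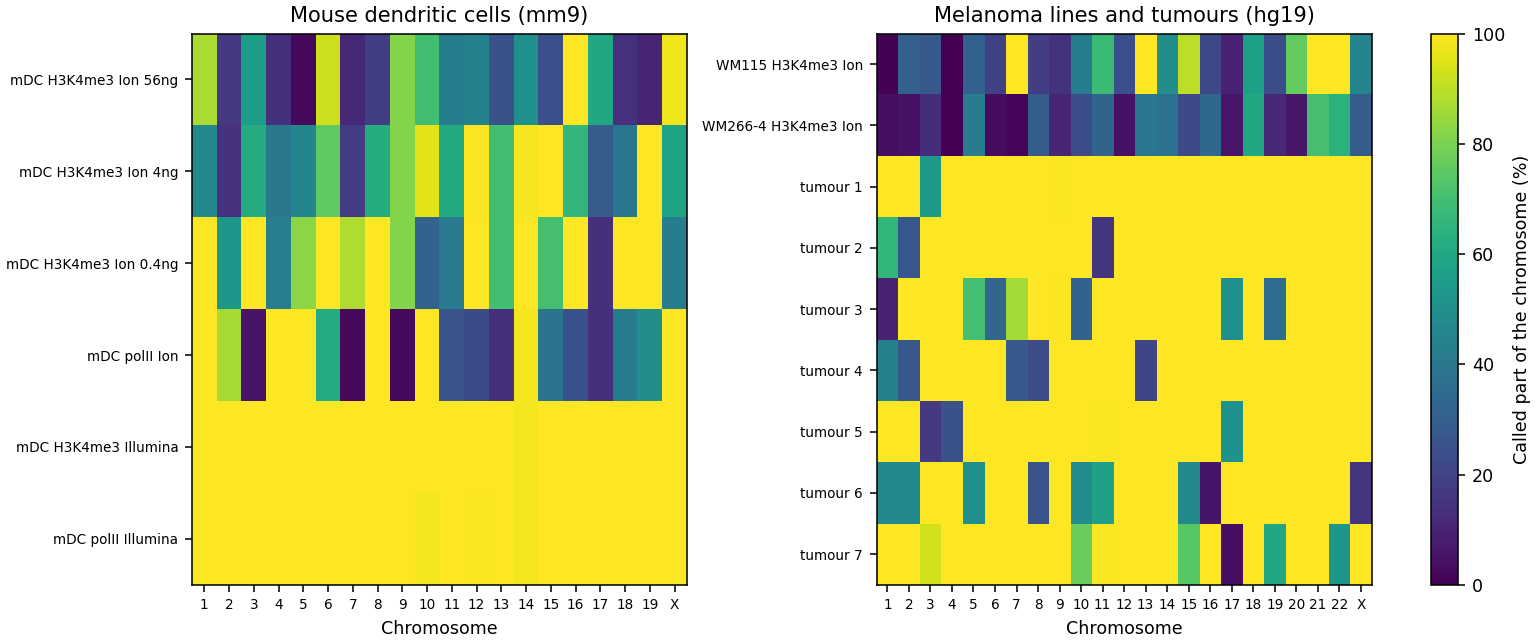
Part of each chromosome (columns) over which each region list (lines of the grid) was called, in percent of the furthest position reached by any list of the species, from dark (0) to yellow (100). The Illumina lists reached nearly every chromosome end, whereas WM266-4 covered 19.2% of the genome.

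The first comparison asked how far semiconductor sequencing finds the H3K4me3 regions of an Illumina library. Within the 1247 Mb called in both, 59.6% (58.7 to 60.5) of 11907 Illumina regions were overlapped by a region at 56 ng, against 2.1% by chance. In the other direction 98.1% of 6625 Ion Torrent regions lay on an Illumina region. Strong regions were shared and weak ones were not: 6.21% of the Illumina regions in the lowest 10% by score were found, and 99.2% in the top 10%. Illumina regions that were found had a median width of 1420 bp, and those that were not 677 bp. The strongest Illumina region with no Ion Torrent region within 5 kb was a 100 bp segment at X:139917550-139917649 with a score of 8656, and the next were at 9:24346476-24346604 and 9:75016177-75016277. All 3 were at most 129 bp wide and are uncertain. Regions in the 56 ng list alone were few, 71 with no Illumina region within 5 kb, and the strongest was at 12:53198448-53199517 with a score of 67.7. With the uncalled ends counted as absent, the share found fell to 23.8%. With both lists shortened by score to the same length it rose, as given with the alternatives below. The share thus depends on the lengths of the lists, 11907 and 6625 regions in the shared stretch, and depth was unknown.

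For Pol II, 44.1% (43.4 to 44.9) of 16997 Illumina regions were overlapped by an Ion Torrent region, against 2.36% by chance, and 74.8% of 11743 Ion Torrent regions by an Illumina one. The share found did not rise steadily with the score of the Illumina regions: it was 31.9% in the lowest of 10 score groups, 24.9% in group 4, 78.7% in group 9 and 74.7% in the top group. Among Ion Torrent Pol II regions the top 10% by score was the least shared of the 10 score groups, at 48.6%. The strongest Ion Torrent regions without an Illumina region were 3 segments on the X chromosome, at X:146999360-146999466, X:45732689-45732796 and X:32098245-32098348. The strongest Illumina Pol II region that Ion Torrent lacked was X:139917549-139917656, the locus that also led the H3K4me3 list, with a score of 10241. Over whole chromosomes the share of Illumina Pol II regions found was 24.1%. It rose with both lists shortened to the same length and fell with the better part of each list by score.

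Pol II and H3K4me3 occupied many of the same places on each platform. On Illumina 44.4% of H3K4me3 regions carried Pol II, with 27.5% in the lowest 10% by score and 87.5% in the top 10%. On Ion Torrent 51.3% of the regions at 56 ng did, with 28.7% and 83.2% in the same groups. Chance overlap was 3.45% and 2.45%.

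The input series asked how much of the H3K4me3 pattern is found again with less material. Of 5241 regions at 56 ng, 90.5% (89.7 to 91.3) were found at 4 ng, and of 5290 regions, 89.3% (88.5 to 90.1) at 0.4 ng, against 2.38% and 5.43% by chance. The order of both amounts depended on how the lists were cut. With every list shortened to the shortest it stayed, at 86.6% at 4 ng and 64.7% at 0.4 ng. With the better part of each list by score it turned, at 87.2% and 97.1%. All regions of the top 10% by score were found at both amounts, and 65.5% and 69.6% of the lowest 10%. The lists differed in what they added. At 4 ng 89.2% of 5554 regions were also in the 56 ng list, but at 0.4 ng 29.8% of 18431 were, with 84.3% in the top 10% by score and 9.54% in the lowest. Regions at 0.4 ng that 56 ng lacked had a median width of 793 bp, and shared ones 1488 bp. The strongest regions found at 0.4 ng and absent at 56 ng were on the X chromosome, at X:70299182-70299410, X:50547488-50547794 and X:56195153-56195450. These were 229 to 307 bp wide. Those that 4 ng added were led by X:57801137-57801248, 112 bp wide. The region at 1:64650289-64650398, 110 bp wide, was among the 3 strongest that 56 ng had and both lower amounts lacked. All of these are far narrower than the medians of their lists and are uncertain. Over whole chromosomes the shares found were 71.7% at 4 ng and 71.5% at 0.4 ng.

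**Figure D2:**
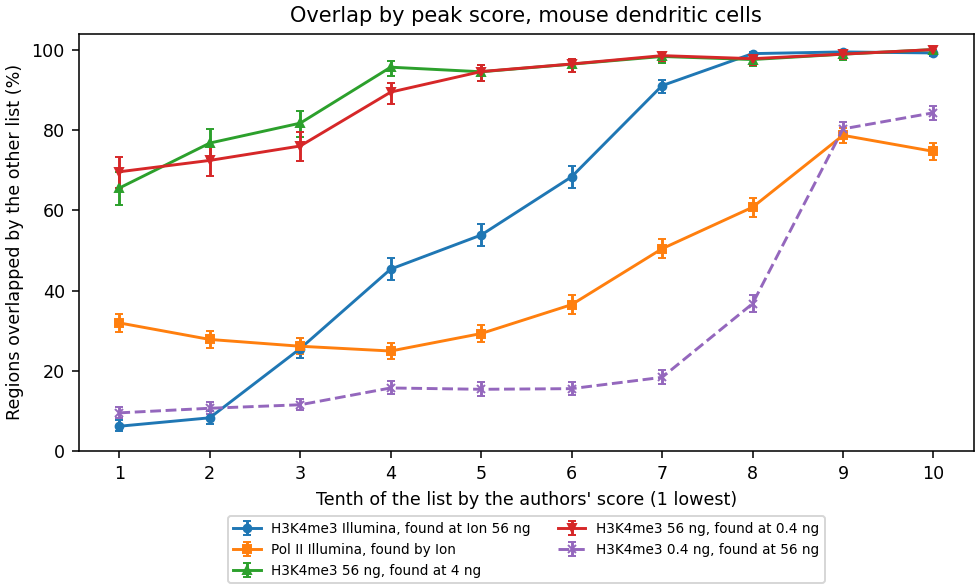
Share of regions overlapped by the other list (percent, vertical) against 10 equal groups of the list by the authors' score (horizontal, 1 lowest), for 5 comparisons in mouse dendritic cells, with 95% Wilson intervals as bars. H3K4me3 regions of the top group were found at 99.2% across platforms and 100% at lower input, whereas 9.54% of the lowest group at 0.4 ng were in the 56 ng list.

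Between the lines, H3K4me3 differed at pigment cell genes, while most developmental regulators called carried it in each line. Of 3348 promoters called in both, 1757 carried H3K4me3 in both lines, 155 in WM115 alone, 130 in WM266-4 alone and 1306 in neither, and independence would give 1078 in both. Every melanocyte gene called in WM266-4, 4 of 4, had a region: TYRP1 and SLC45A2, which act in melanin synthesis, the melanoma antigen MLANA, and GPR143, a melanosome receptor. None of these 4 had one in WM115, where 2 of 14 melanocyte genes did (RAB27A and OCA2) and SOX10, TYR and DCT did not. Of random lists of 14 promoters in WM115, 0.09% had as few. The 4 of 4 in WM266-4 stood less far apart, with 89.1% of random lists of that size below it. All 12 developmental regulators called in WM115 carried H3K4me3, a count that 99.8% of random lists fell short of. In WM266-4 5 of 6 did, with WT1 the exception, and 80.4% of random lists fell short of that. PAX6 and GATA4 had a region in both lines.

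The strongest promoters in WM115 with no region within 5 kb in WM266-4, among 134, were CDX2, an intestinal homeobox gene, the desmosome gene DSC2, EMB, SNTG2, the neurofilament gene NEFL, NHS, SPEF2, SERTM1, PLXDC2 and ARMC4. In the other direction, among 103, they were SLC45A2, SORBS3, DNAJC15, CLCN4, AKR1E2, the matrix metalloproteinase gene MMP14, ARSD, TAPBPL, TTLL3 and ECHDC3. The score was 315 at CDX2 (region 13:28540435-28543299) and 428 at SLC45A2 (region 5:33984261-33984443). The SLC45A2 region is far narrower than the WM266-4 list's median of 944.5 bp and is uncertain. Mesenchymal genes did not separate the lines in this way, with 7 of 9 called in WM115 and 3 of 3 in WM266-4, LOXL2, CDH2 and VIM among them. T cell, B cell, myeloid and endothelial genes had no region in either line, over 1 to 6 genes called in each. No test is possible with 1 library per line. With uncalled ends counted as absent, 3469 promoters stood in WM115 alone and 427 in WM266-4 alone.

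H3K27me3 marked 4159 promoters in WM266-4 and 1490 in WM115. The 90th percentile count was 49 in WM266-4 and 33 in WM115, and whether the libraries were equally enriched for the mark was not tested. Both lines shared 746 of the marked promoters, more than the 267.7 of independence. TWIST1, a regulator of the mesenchymal state, had 8 counts in WM115 and 143 in WM266-4. The growth factor gene FGF19 had 7 and 161, the basement membrane gene NID2 12 and 161, and ST6GALNAC5 13 and 172. TMEM37, OTOP1, NOTO, KIF17 and GALNT6 were also among the 10 with the largest multiples in WM266-4 of 1297 genes marked there and at or under the median in WM115. Of 307 genes in the reverse class the leaders were IL1RAPL2 with 144 and 10 counts, the Notch target HES5 with 118 and 6, TBX22 with 107 and 9, then KCNN2, LY6H, PDGFA, SSR4P1, ARMCX3, PDZD4 and CNKSR2. The class was rich in X-linked genes, 67 of 307 (21.8%), against 3 of 1297 in the other. The median count of 1001 X-linked promoters was 20 in WM115 and 6 in WM266-4, a ratio of 0.355 after division by the library medians, while the autosomes ranged from 0.689 (chromosome 10) to 1.67 (chromosome 7).

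**Figure D3:**
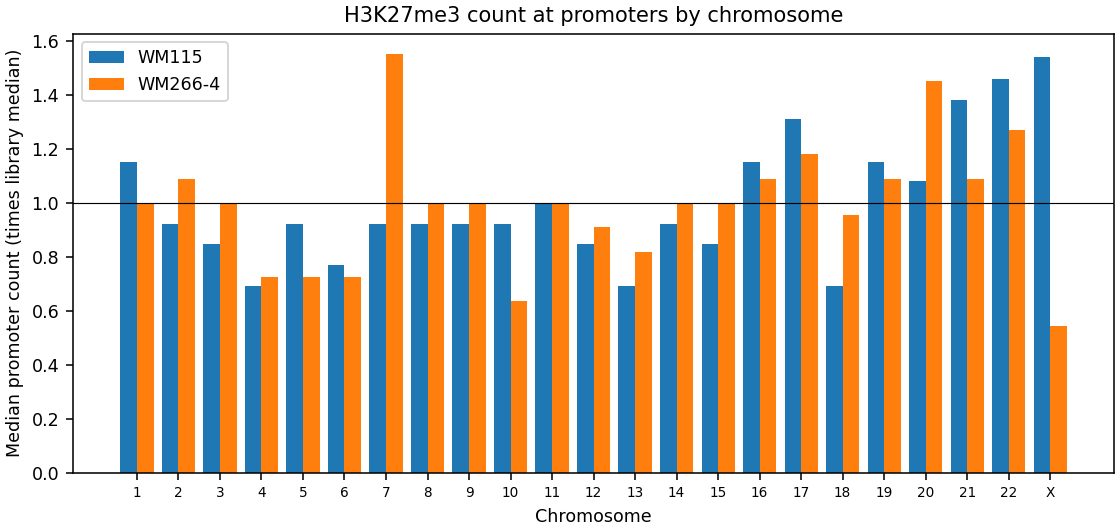
Median H3K27me3 count of the promoters of each chromosome (horizontal), in multiples of the library median (vertical), in WM115 and WM266-4, with a line at 1. The X chromosome stood at 1.54 in WM115 and 0.545 in WM266-4.

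Developmental regulators were marked at 18 of 30 promoters in WM266-4 and 4 in WM115, the highest share of any list in WM266-4 (not when scaled by the total, with 7 of 30 against 4 of 12 neuron and glia genes and 3 of 12 B cell genes), and OLIG2 (29 counts in WM115 and 132 in WM266-4), TBX15 (24 and 147) and FOXF1 (20 and 106) were examples. Pan-leukocyte genes were marked at 7 of 16 promoters in WM266-4 and 0 in WM115, with CD53 at 94 counts in WM266-4 and 0 in WM115. Endothelial genes were marked at 7 and 1 of 14, T cell genes at 7 and 1 of 18, fibroblast genes at 5 and 0 of 14, neuron and glia genes at 5 and 1 of 12, keratinocyte genes at 5 and 1 of 16, mesenchymal melanoma genes at 6 and 3 of 20, myeloid genes at 4 and 1 of 16 (0 and 1 when scaled by the total, which turns the direction) and B cell genes at 3 and 0 of 12. With counts scaled by the total, the marked promoters in WM266-4 numbered 2 for pan-leukocyte, T cell and fibroblast genes, 3 for endothelial and keratinocyte genes and 4 for mesenchymal melanoma genes, against 0 to 2 in WM115. Cancer-testis genes went the other way, with 1 of 20 marked in WM266-4 and 5 in WM115 (1 and 2 when scaled by the total), MAGEA3 (55 counts in WM115 and 14 in WM266-4) among them. Of these 20 genes 14 were X-linked, with 4 marked in WM115 and 0 in WM266-4, and the 6 autosomal ones had 1 marked in each line. Melanocyte genes were marked at 2 and 0 of 20, cell cycle genes at 1 and 0 of 20, adhesion genes at 3 and 2 of 20, antigen presentation genes at 0 and 1 of 20, and housekeeping genes at 0 and 1 of 18.

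Set against matched random lists, the median fold of WM266-4 over WM115 was high for fibroblast genes (3.32, percentile 99.3), neuron and glia genes (3.04, percentile 98) and pan-leukocyte genes (2.64, percentile 97.6). It was low for cancer-testis genes (0.548, percentile 0.41), but among random lists matched also on X linkage, chosen after seeing the data, the percentile was 44.3. Cell cycle genes (0.604, percentile 7.33) and antigen presentation genes (0.621, percentile 9.58) were low too, at percentiles 5.67 and 7.31 when matched also on X linkage. Many antigen presentation genes lie in a part of chromosome 6 with median counts of 2 in WM115 and 1 in WM266-4. The fold of that list thus rests largely on counts near the floor. Among fibroblast genes, DCN (0 counts in WM115 and 7 in WM266-4) and LUM (0 and 4) were also near the floor, while COL1A1 (35 and 99) was not. T cell genes stood at 2.03 (percentile 93.7), endothelial genes at 2.1 (88.7), adhesion genes at 0.918 (22.8), melanocyte genes at 0.844 (31.5) and housekeeping genes at 0.763 (25.4). The fold of developmental regulators was 2.21, at percentile 82.8. Scaling by the total count in place of the median lowers every log2 ratio by 0.46. It turns the direction for mesenchymal melanoma genes (1.36 to 0.99), B cell genes (1.01 to 0.73), myeloid genes (1.05 to 0.765) and keratinocyte genes (1.32 to 0.959), and leaves 1761 marked promoters in WM266-4 and 768 in WM115, with developmental regulators at 7 and 1. These are counts of 1 library per line, so they describe the libraries.

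At the same promoters, both marks met at 335 genes in WM115, close to the 311.1 of independence, and at 283 in WM266-4, below 401.1. H3K27me3 marked 13.0% (11.6 to 14.4) of WM266-4 promoters with H3K4me3 and 25.6% (23.5 to 27.7) of those without. In WM115 the shares ran the other way, at 6.42% (5.78 to 7.11) and 5.34% (4.68 to 6.09). Those 2 intervals overlap slightly, which does not test the difference. Genes with both marks were led by POLR2J3, TBC1D4, INSM2 and the adhesion gene ZYX in WM115, and by TRPC4, the VEGF receptor gene FLT1, EPSTI1 and the tight junction gene OCLN in WM266-4, which also held GATA6. At 57 promoters WM115 had H3K4me3 alone and WM266-4 H3K27me3 alone, and at 3 the reverse. Equal enrichment of the 2 H3K27me3 libraries was not tested, so this difference in number cannot be read as one between the lines. Of the 155 promoters with H3K4me3 in WM115 only, 57.4% were marked by H3K27me3 in WM266-4, against 12.4% of the promoters with H3K4me3 in both lines. For the 130 of WM266-4 the shares in WM115 were 6.15% and 5.98%. The 155 and the 130 lack H3K4me3 in the other line by selection, which the promoters with it in both lines do not. Among all promoters called in a line, those without H3K4me3 were marked at 25.6% in WM266-4 and 5.34% in WM115. The class of 57 was led by CDX2 (13 and 79 H3K27me3 counts in WM115 and WM266-4), DSC2, SNTG2, SERTM1, UNCX (26 and 141) and NEFL, and held WASF3 (0 and 84), the kidney and gonad regulator WT1 (1 and 50), PLXDC2 and SYT9. The class of 3 held RSAD2, an interferon-induced gene, VENTXP7 and a predicted gene with no official symbol. Both counts depend on the mark chosen: with H3K27me3 scaled by the total, 34 and 0 remained, and with a mark at 2 times the median the class of 3 became 17.

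The tumours shared most of their H3K4me3 promoters. Regions lay on 58.5% ± 2.75 (SD, n = 7) of the promoters called in each. Of 9023 promoters called in all 7 tumours, 4285 (47.5%) carried H3K4me3 in every tumour and 2993 in none, where independent tumours would give 179 and 23.5. Pairs of tumours shared 82.1 to 89.1% of the promoters marked in either, with a median of 86.8%. The melanosome gene PMEL, whose window overlaps that of CDK2, carried it in 7 of 7 tumours, as did ERBB3, S100B and GPNMB, and the mesenchymal genes VIM, ZEB1, CDH2 and TWIST1. SOX10, RAB27A, KIT and MC1R were found in all 6 tumours where each was called. Other pigment cell genes varied: SLC45A2 was found in 6 of 7, MLANA in 4 of 7, TYR in 3 of 5 and TYRP1 in 2 of 7. The share of melanocyte genes ran from 50% in tumour 1 to 93.8% in tumour 6. MITF, the master regulator of the lineage, was in 0 of 6, but its window covers a single start of a gene with several. A region that covers at least 50% of the promoter was found in all 7 at 1605 genes.

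Immune genes set the tumours apart from each other. T cell genes carried H3K4me3 at 83.3%, 100% and 76.5% of the called promoters in tumours 3, 4 and 7 and at 11.1 to 33.3% in the other 4. Melanocyte genes stood at 85%, 88.2% and 89.5% in those 3 tumours and at 93.8% in tumour 6, against 50 to 55.6% in tumours 1, 2 and 5. CD3D, CD3E and CD3G, the signalling chains of the T cell receptor, were found in tumours 3, 4 and 7 and not in tumours 1 and 5. Myeloid genes stood at 87.5% in tumour 1 and 71.4% in tumour 2, at 50% in tumour 4 and at 0 to 33.3% elsewhere. CD163, a macrophage receptor, and LYZ were found only in tumours 1 and 2 of the 7 called. Pan-leukocyte genes stood at 75% or more in 6 tumours and at 25% in tumour 5. The shares rest on partly different genes, since 9 to 18 T cell genes were called per tumour and 4 in all 7.

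**Figure D4:**
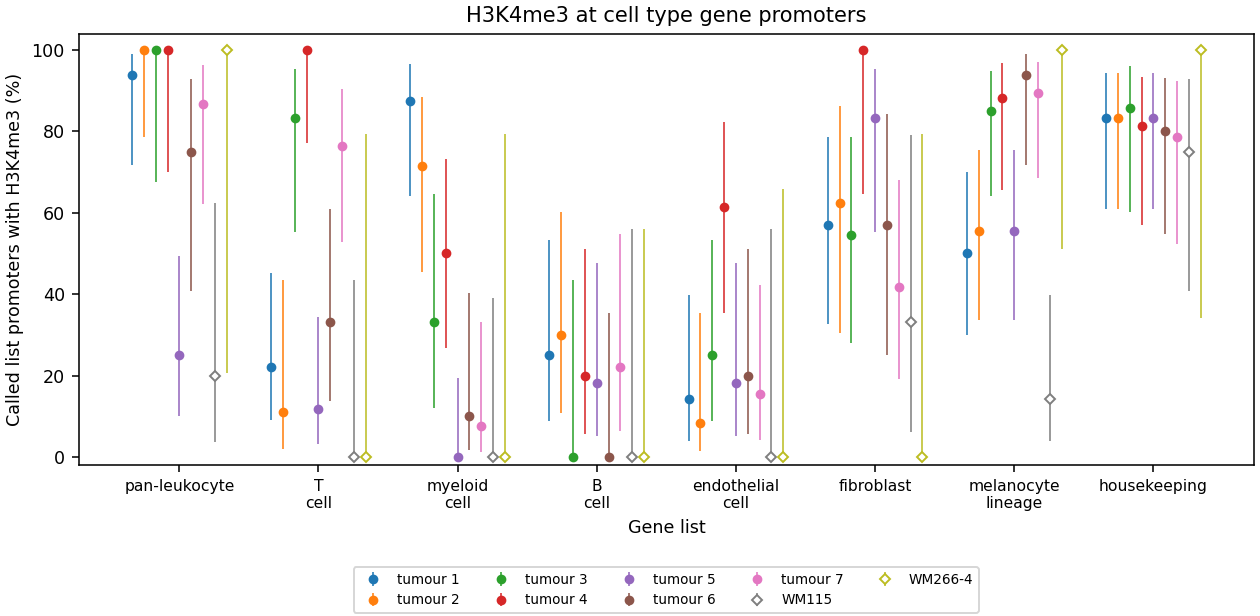
Share of the called promoters of each gene list with H3K4me3 (percent, vertical) for 8 gene lists (horizontal) in the 7 tumours (filled circles) and in WM115 and WM266-4 (open diamonds), with 95% Wilson intervals as bars. T cell genes stood at 76.5% or more in tumours 3, 4 and 7 and at 0 in WM115 and WM266-4, where 5 and 1 of them were called.

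Against the lines, T cell, endothelial and fibroblast genes had a higher share of called promoters with H3K4me3 in every tumour than in either line. Keratinocyte, developmental and cell cycle genes had a lower one. The shares rest on different genes, since the lines were called at few genes of each list. At the endothelial genes called in a line (VWF, ERG and CLDN5) only tumours 4 and 5 had a region. At the T cell genes called in a line (CD5, CD6, CD4, IL7R and UBASH3A) tumours 5 and 6 had none. T cell genes stood at 48.3% ± 37.2 (SD, n = 7) in tumours and at 0 in the lines. This was higher in 7 of 7 tumours than in either line over the genes called in each, but not over the same genes. Endothelial genes stood at 23.2% ± 17.7 against 0 and fibroblast genes at 65.2% ± 19.8 against 16.7%, again in 7 of 7 over the genes called in each. COL1A1, PDGFRA and PDGFRB were found in every tumour where they were called, but DCN in 2 of 7 and LUM in 1 of 7. None of these fibroblast genes was called in either line. Keratinocyte genes stood at 31.3% ± 7.32 against 66.7%, developmental regulators at 65.6% ± 13.6 against 91.7%, and cell cycle genes at 83.6% ± 2.8 against 94.4%. Here too the genes differed. WM115 was called at 6 keratinocyte genes and 12 regulators and WM266-4 at 3 and 6, but the tumours at 13 to 15 and 22 to 30. Each of these 6 lists had the smallest p that doubling the one-sided exact permutation p allows (two-sided p = 0.0556, adjusted p = 0.148). On the absolute difference the exact permutation p was 0.0278 for fibroblast, keratinocyte and cell cycle genes (adjusted p = 0.148), 0.0556 for developmental regulators (adjusted p = 0.222), 0.111 for T cell genes (adjusted p = 0.254) and 0.167 for endothelial genes (adjusted p = 0.333). The other lists did not separate the groups in this way. Melanocyte genes stood at 73.9% ± 19.2 against 57.1%, mesenchymal melanoma genes at 86.2% ± 8.53 against 88.9%, pan-leukocyte genes at 82.9% ± 27.2 against 60%, B cell genes at 16.5% ± 11.9 against 0 and myeloid genes at 37.1% ± 33.8 against 0. Neuron and glia genes stood at 52.3% ± 16.4 against 50%, cancer-testis genes at 18.5% ± 11.5 against 39.3%, antigen presentation genes, many of which lie in a part of chromosome 6 nearly empty of both marks where housekeeping genes also lacked a region, at 40.3% ± 5.91 against 39.3%, adhesion genes at 71.0% ± 6.1 against 85.7% and housekeeping genes at 82.2% ± 2.42 against 87.5%. The lines themselves lay far apart for melanocyte genes (14.3% in WM115 and 100% in WM266-4), pan-leukocyte genes (20% and 100%) and neuron and glia genes (100% and 0), and without WM266-4 these differences were 59.6, 62.9 and -47.7 points in place of 16.8, 22.9 and 2.3. Over the promoters of both lines pooled, melanocyte and pan-leukocyte genes each stood at 33.3%. The line means rest on few promoters, 6 for T cell genes, 5 for endothelial genes, 4 for fibroblast genes and 9 for keratinocyte genes. Both lines also come from the same patient. Over all alternatives the difference, in points, ranged from 0 to 57.1 for T cell genes, 0 to 25.7 for endothelial genes, -12.1 to 52.9 for fibroblast genes, -64.8 to 8.04 for keratinocyte genes, -70.8 to 28.3 for developmental regulators and -51.2 to 51.4 for cell cycle genes. With every list shortened to the shortest, T cell and endothelial genes were at 0 and fibroblast genes turned to -12.1; with the better part of each list by score T cell genes were at 4.23 and cell cycle genes turned to 28.4, a promoter within 2.5 kb left endothelial genes at 1.83, a region covering 50% of the promoter turned cell cycle genes to 6.93, and with uncalled ends counted as absent keratinocyte, developmental and cell cycle genes turned to 8.04, 28.3 and 51.4. Without WM266-4 fibroblast genes were at 31.9 and cell cycle genes at -5.26.

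Few single genes separated tumours from lines among the 2833 promoters called in all 9 libraries. In all 7 tumours and neither line there were 3, TRIM22, an interferon-induced antiviral gene, and APBB1IP, an adaptor of leukocyte integrins, being those with a name the rule allows; the other was a predicted gene with no official symbol. In both lines and no tumour there were 11, led by the Wnt regulator NKD2, WASH7P, the telomerase gene TERT, ARHGDIG, TBX1, NTN3, PLAC2, PPAP2C, HCN2 and WASH5P. Most of these ranked low by score within the line lists. The mean rank percentile, where higher is stronger, was 52.9 for NKD2, 24.1 for TERT, 16.1 for TBX1 and 0.977 for WASH5P. TRIM22 and APBB1IP stood at 38.6 and 35.8 in the tumour lists. Presence or absence at such weak regions is uncertain. The WASH genes belong to a family of near-identical copies and are uncertain. Of the 36 ways to set 2 of the 9 libraries apart, 10 gave at least 3 genes in the first class, with 10 as the highest, and 2 gave at least 11 in the second, with 13 as the highest other. Leaving out WM266-4 raised the counts to 78 and 57, and leaving out tumour 5 or tumour 7 raised the first to 8 and 10. Each list left out can also change the promoters called in all the rest, so these counts are not over the same 2833. WM266-4 was called at 3824 promoters and WM115 at 9114, so more promoters were examined without WM266-4.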

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

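The tests of list sensitivity, of an X copy number change, of scaling and of overlap with Illumina regions were chosen after the result was seen, as were the width comparison with Illumina-supported regions and the limit on the Pol II share, each of which overrode a bound set beforehand.

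Immune gene promoters differed between tumours: T cell genes stood at 76.5 to 100% in tumours 3, 4 and 7 and at 11.1 to 33.3% in the others, myeloid genes were highest in tumours 1 and 2, and pan-leukocyte genes at 25% in tumour 5 lay far below the other 6, whose lowest was 75%. The values argued against a difference in list sensitivity that moves all promoters alike as the source. The share over all promoters ranged over 7.59 points and the T cell share over 88.9, although a short list also varies more by counting error. The largest Pearson r of 3 lists with the share over all promoters was 0.0874, for T cell genes (exact permutation p = 0.823, n = 7). The largest rho was 0.408, for pan-leukocyte genes (exact permutation p = 0.371, n = 7). A difference in sensitivity to weak regions alone stays open, since the share over all promoters does not measure it. Second lists of 16 genes each, fixed before their values were seen, gave a Spearman rho with the first of 0.821 for T cell genes (exact permutation p = 0.0341, adjusted over 6 relations 0.102, n = 7) and 0.857 for myeloid genes (r = 0.969, exact p = 0.0238 and 0.00437, adjusted 0.102 and 0.0262; r = 0.951 without the 2 farthest tumours). The T cell relation rests on the contrast of tumours 3, 4 and 7 with the rest, too few on each side to test within, CD8A and BCL11B had a region in tumours 1 and 5 too, and no relation of the T cell and myeloid shares was detectable (r = -0.149, rho -0.0714, exact p = 0.748 and 0.906, n = 7). Differing amounts of T cells and myeloid cells in the tissue are thus a candidate explanation, as a hypothesis, but melanocyte genes were also higher in tumours 3, 4, 6 and 7 (85 to 93.8%) than in tumours 1, 2 and 5 (50 to 55.6%), so a difference between tumours that moves both lists stays open; in the lines 0 of 6 T cell, 0 of 7 myeloid and 2 of 6 pan-leukocyte promoters called had a region, and no sort of cells is given in the labels.

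H3K27me3 at X-linked promoters was lower in WM266-4 than in WM115, with a ratio relative to the autosomes of 0.355 (95% bootstrap interval 0.295 to 0.414 over 2000 draws of promoters). A change in the number of X copies with an unchanged mark cannot be told apart from a change in the mark, since neither copy number nor the mark on single copies was measured. Scaling or depth would move other chromosomes as far, and the lowest autosome stood at 0.689. A domain over the whole X chromosome in WM115 cannot be told apart from one over part of it, since 5 equal groups of the X-linked promoters by position stood at 1.15, 1.31, 1.77, 2 and 1.73 times the autosomal median, the lowest between the bounds set for either reading. With 1 library each, neither open reading is favoured.

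At 0.4 ng, 12934 of 18429 regions lay outside the 56 ng list. The values argued against more sensitive detection of regions that the Illumina library also shows as their main source, since 9.87% (Wilson interval 9.37 to 10.4) were in its list; more sensitive detection of regions that this list lacks stays open. Pol II sites missed at 56 ng could account for few: overlap with Illumina Pol II was 2.07 times chance, just past the bound set beforehand, but covered 5.19% (4.8 to 5.61) of the 11657 regions in neither H3K4me3 list against 2.51% by chance. Noise from few amplified fragments cannot be told apart from real weak regions by width, since 99.8% of those regions were narrower than the median of shared ones, as that reading needed, but so were 96.2% of the 1277 regions that the Illumina list did hold. No biological explanation was tested, as the cells were the same by label.

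Endothelial genes in tumour 4, at 61.5%, lay far above the other tumours, at 8.33 to 25%. Tumour 4 also stood highest for T cell genes (100%), fibroblast genes (100%), keratinocyte genes (46.2%) and all promoters (62.2%). Developmental regulators in tumour 1, at 36.7%, lay far below the other tumours, at 62.1 to 77.3%. With the pan-leukocyte share these were 3 of 19 quantities checked by Dixon's criterion over the 7 tumours, and chance alone marks about 1 in 20 groups. Segments on the mitochondrial genome and separate contigs, which the comparisons leave out, made up 2.49% of the WM115 list, 4.27% of the WM266-4 list and at most 1.23% of a tumour list.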

How the results depend on the processing

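Of 514 values recomputed under 25 alternatives, 14 planned and 11 chosen after seeing the data, 390 were kept, 96 moved and 28 turned direction. Shares and percentiles were kept when they stayed within their error, and counts when they stayed within 1.5 times. Differences between tumours and lines were judged by direction alone, so a fall to 0 or near it counts as kept. The overlap shares and the counts rest on single lists whose depth is unknown. By the doubled p no list comparison of tumours and lines can pass a threshold, so kept directions there say nothing about stability; by the p from the absolute difference 0 of 16 lists passed after adjustment. Random lists matched also on X linkage moved the cancer-testis percentile to 44.3. Except where the construction is named, the cause was not tested. No paired analysis was possible because the tumours carry numbers that no line shares and the other libraries are single. The mouse gene lists and, for H3K27me3, a promoter within 2.5 kb and a region covering 50% of the promoter were not run, since they need an annotation not used here or peaks in place of counts.

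With the better part of each list by score, the Illumina share found was 58.3% for H3K4me3 and 36.04% for Pol II, and the 56 ng share found was 87.2% at 4 ng and 97.1% at 0.4 ng. H3K4me3 in WM266-4 only became 234 and in both lines 1151, the smaller class of opposite marks 10, both marks 50 in WM115 and 50 in WM266-4, and H3K27me3 426 in WM115 only, 1760 in WM266-4 only and 319 in both, fewer marks by construction. Genes in all 7 tumours became 2077 (23.02%), those in tumours and neither line 14 and those in lines and no tumour 20. The tumour minus line share turned for neuron and glia genes (-19.7 points), cancer-testis genes (14.5) and cell cycle genes (28.4).

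With lists shortened to the shortest, the shares were 88.1%, 51.1%, 86.6% and 64.7% in the same order. WM115-only H3K4me3 became 248, both marks 155 in WM115 and 117 in WM266-4, H3K27me3 1088 in each line only, by construction, in place of 3413 in WM266-4 and 744 in WM115, and 402 in both, and the share in all 7 tumours 40.3%. A single list, 1 of 16, stood higher in tumours in place of 9, since tumour lists were thinned over a far longer stretch. Melanocyte (-42.3), pan-leukocyte (-48.2), fibroblast (-12.1), neuron and glia (-34.5) and antigen presentation genes (-26.6) turned.

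An overlap of 50% of the shorter region gave 40.7% for Pol II and 88.0% at 0.4 ng. The other direction gave 98.1% for H3K4me3, 74.8% for Pol II, 89.2% at 4 ng and 29.8% at 0.4 ng. A promoter within 2.5 kb gave 5 in the smaller opposite class and 49.5% in all 7 tumours, and turned antigen presentation genes (-22.6). A region covering 50% of the promoter gave H3K4me3 318 in WM115 only, 291 in WM266-4 only and 983 in both, 11 in the smaller opposite class, both marks 209 in WM115 and 116 in WM266-4, 1605 genes (17.8%) in all 7 tumours, 24 in tumours and neither line and 45 in lines and no tumour; pan-leukocyte (-31.9) and cell cycle genes (6.93) turned. Leaving out each tumour gave 47.6 to 49.1% of promoters in all remaining tumours and 3 to 10 genes in tumours and neither line. Both rest on called promoters that can change with the tumour left out. The differences ran from -0.648 to 7.32 points for neuron and glia genes and from -0.172 to 2.72 for antigen presentation genes. Leaving out tumour 3 or 5 turned the former (-0.0926 and -0.648), and tumour 4 or 6 the latter (-0.172 and -0.0546).

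With uncalled ends counted as absent, which by construction lowers every short list, the shares were 23.8%, 24.1%, 71.7% and 71.5%. H3K4me3 became 3469 in WM115 only and 427 in WM266-4 only, the opposite classes 467 and 11, the share in all 7 tumours 18.6%, genes in tumours and neither line 1767, and lists higher in tumours 16. Mesenchymal melanoma (45.7), keratinocyte (8.04), developmental (28.3), cancer-testis (6.79), cell cycle (51.4), adhesion (37.1) and housekeeping genes (51.6) turned. A stretch ended at the first segment over 1 Mb turned cancer-testis genes (2.43). Unmerged segments gave 62.7% for H3K4me3, 53.4% for Pol II and 92.1% at 4 ng, and segments of up to 30 kb 47.0% for Pol II.

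An H3K27me3 mark at 2 times the median gave 17 in the smaller opposite class, both marks 992 in WM115 and 444 in WM266-4, 2230 marked in WM115 only and 2094 in both. At 4 times it gave 0, 158 with both marks in WM115, 318 marked in WM115 only and 370 in both. Scaling by the total gave opposite classes of 34 and 0, both marks 174 in WM115 and 136 in WM266-4, and 475 marked in WM115 only, 1468 in WM266-4 only and 293 in both. Restricting tumours to genes called in all 7 turned mesenchymal melanoma (11.1) and antigen presentation genes (-11.7). Without WM266-4, 78 genes stood in tumours and not WM115 and 57 in WM115 and no tumour, over a larger set of called promoters. Mesenchymal melanoma (8.41), neuron and glia (-47.7) and housekeeping genes (7.22) turned.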

Other observations

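The test of H3K27me3 by tumour H3K4me3 was fixed before its result was seen, whereas the genes named for width and the stretch of chromosome 6 were chosen after their values were seen.

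The widest H3K4me3 regions of the tumours lay on a recurring set of promoters. Among the 100 widest promoter regions of each tumour, the antiproliferative gene BTG1 and TFAP2A, a neural crest and pigment cell transcription factor, were found in 7 of 7 tumours, with median widths of 9901 and 11474 bp. DUSP6, ZFP36L1 and PCDH7 were found in 6 of 7, with medians of 7757, 6481 and 9285 bp. BHLHE40, DUSP4, GPBP1, NR4A3, PHLDA1, SPRED1 and TRIB2 were in 5 of 7, ARRDC3, MAF, PCGF2 and its neighbour PSMB3 in 5 of the 6 tumours in which they were called, and TSC22D2 in 5 of 5. These are all the genes with an official symbol found in at least 5 tumours. PCDH7 ranged from 1759 to 10460 bp, so width differed between tumours. No test of these genes as a group was made.

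The part of chromosome 6 between 29 and 34 Mb, which holds the HLA genes, was nearly empty of both marks. H3K4me3 was found at 6.81% of 1512 called promoters summed over the tumours, against 65.2% of 6326 on the rest of the chromosome. The median H3K27me3 count of its 216 promoters was 2 in WM115 and 1 in WM266-4, against 12 and 11 on the rest. TAP1, TAP2, PSMB8, PSMB9 and HLA-E carried H3K4me3 in 0 of 7 tumours, while B2M on chromosome 15 carried it in 7 of 7. Of the segments on contigs in the 9 human lists, 15.7 to 28.8% were on contigs assigned to chromosome 6. These segments were left out of every comparison. The values of the antigen presentation list, and of AIF1 among the myeloid genes, include this stretch, as do those of TUBB and RPS18 among the housekeeping genes, which were also found in 0 of 7 tumours. Loss of reads to alternate contigs of this stretch in mapping was not tested, so these values do not show that its promoters lack the marks.

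A hypothesis that promoters without H3K4me3 in tumours carry H3K27me3 in melanoma lines was tested. Of 2993 promoters with H3K4me3 in no tumour, 21.6% (Wilson interval 20.1 to 23.1) were marked by H3K27me3 in WM266-4, against 6.44% (5.74 to 7.22) of 4285 promoters with it in all 7, 3.35 times as often. In WM115 the shares were 5.41% (4.66 to 6.28) and 2.75% (2.3 to 3.29). The highest shares were at the 1745 promoters with H3K4me3 in 1 to 6 tumours, 43.2% (40.9 to 45.5) in WM266-4 and 12.7% (11.2 to 14.3) in WM115. H3K27me3 in a line may therefore mark promoters that vary between tumours more than those that lack H3K4me3 in all of them. This second reading was noticed in the same values and is a hypothesis. The chromosome 6 stretch of 29 to 34 Mb was called in every tumour and is included here. Its promoters mostly lacked H3K4me3 and had median H3K27me3 counts of 2 in WM115 and 1 in WM266-4. They can lower the marked share of the 2993 promoters, which would favour the second reading.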
